A study of Mus musculus with 8 samples.

How the data were processed

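RNA of full-thickness skin from mouse embryos at embryonic day 17.5 was extracted with Trizol and purified on columns, and 100 ng of total RNA per sample was amplified with a whole-transcript kit, after which 5.5 μg of cDNA was fragmented and labelled with biotin, per the labels' protocols. Each of the 8 samples was hybridised to 1 single-colour Affymetrix array. The deposited log2 values were made with RMA in Affymetrix Expression Console, per the submitters' processing notes; RMA corrects background, quantile-normalizes arrays to each other and summarizes the probes of a transcript cluster on the log2 scale. Versions, the annotation build and any filter are not given in the sources used here. Quantile normalization gives all arrays nearly the same distribution, so a shift of all transcripts together cannot be seen, and summarizing over probes hides the loss of single exons. Scanner files were not used here.

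Samples were grouped by the genotype and title in their labels into 4 control and 4 Pparg null arrays. The table held 35556 transcript clusters. The platform annotation gave 1 gene symbol to 21789 of them, several to 1621 and listed none for 12146; no gene was named from a cluster with several symbols. Symbols were updated through the gene ID for 21698 clusters found in a RefSeq gene table of assembly GRCm38.p6, and 91 kept the symbol of the platform annotation. Because the build behind the annotation is not named, no coordinates are given. A cluster entered the test when it lay above the 30th percentile of its array on at least 4 of 8 arrays, and the cluster with the highest mean stood for a gene with several, which left 15174 of 19938 genes; 917 tested genes had more than 1 cluster.

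Differences are log2 values on the arrays labelled Pparg null minus control, fitted without covariates by limma (version 3.58.1, R 4.3.3, with statmod 1.5.0 for the block) with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 48 lists with at least 3 tested members, with an estimated correlation and with fry as alternatives. The lists cover pathways, skin compartments and other cell types that full-thickness skin can hold, from general knowledge and not from these samples. Some genes stand in more than 1 list. Differences of single values were tested by exact two-sided permutation over all 70 assignments of 8 arrays to 4 and 4. On simulated data for this comparison, with 15174 genes and the arrays' spread, 100 genes were changed by 0.5 and 100 by 1 on the log2 scale. The limma step recovered 81.6% of the former and 97.6% of the latter, with 4.58% false calls and 0 of the wrong sign. The simulated genes varied independently. In the real data 18 genes passed, which makes the adjusted threshold stricter, so these shares are not the power of the real comparison. The camera step found 100% of simulated lists shifted by -0.2 and called 2% of unchanged ones; the simulated genes were independent of each other, unlike real ones.

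The genes named are Pparg, the 12 largest falls and 12 largest rises among genes past the threshold whose groups do not overlap (leaving out predicted genes, clones, small RNAs, receptor and immunoglobulin families and sex-linked genes), and examples from the up to 5 members of each list with the smallest unadjusted p. Only 1 gene rose past the threshold. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were other filters on dim clusters (none, or the 50th percentile), centring each array, cyclic loess, a trended and robust prior, array weights, a block for the replicate number, the mean of a gene's clusters, every cluster on its own, stricter thresholds, and leaving out each array in turn. Added after the data were seen were a fit without control array 1 and labelled-null array 4, and fits with each array's Xist value or its mean over the suprabasal epidermis list as a covariate.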

Results

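Transcripts were measured in full-thickness skin of mouse embryos at E17.5, on 8 Affymetrix whole-transcript arrays. The arrays carried 4 RNAs from embryos labelled wildtype for PPARgamma, called control here, and 4 RNAs from embryos labelled PpargΔ/Δ, called Pparg null, all of a mixed C57BL6/SV129 background. Pparg encodes PPARgamma, the nuclear receptor that drives adipocyte differentiation, and the series asked how the skin transcriptome differs without it. Full-thickness skin holds epidermis, hair follicles, dermis and the fat layer below, so each value is an average over these tissues. The labels give each array an individual RNA but no litter or sex, and p-values therefore measure the spread between these RNAs. The array medians of the deposited log2 values lay between 6.93 and 6.96. Pairs of arrays correlated across all 35556 transcript clusters at r = 0.989 to 0.994, both within and between groups, and no pair held identical values. Precision is limited by the 4 arrays per group.

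The Pparg transcript cluster (10540897) was not lower on the arrays labelled Pparg null. Its log2 value was 8.94 ± 0.13 (SD, n = 4) in control skin and 9.12 ± 0.10 (SD, n = 4) on the arrays labelled Pparg null, a difference of 0.18 with a 95% confidence interval of 0.01 to 0.35. The 4 control values ran from 8.79 to 9.06 and the 4 others from 8.98 to 9.19, so the groups overlapped (exact two-sided permutation p = 0.0857, with 0.0286 the smallest that 4 against 4 can give; limma p = 0.0393, adjusted p = 0.9995). The labels do not say which part of the gene was deleted, and a cluster that reads outside the deleted part checks nothing about the labels. Every direction below is therefore given for the arrays labelled Pparg null.

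Cd36, Fabp4, Lpl and Aqp7, genes of lipid handling in adipocytes, were lower on the arrays labelled Pparg null. Cd36, a fatty acid transporter, was at 9.82 ± 0.09 in control skin and 8.90 ± 0.14 on the arrays labelled Pparg null (log2 values, SD, n = 4), a difference of -0.92 (SE 0.077, limma adjusted p = 0.00585). Fabp4, the adipocyte fatty acid binding protein, was 2.19-fold lower, and Lpl, lipoprotein lipase, was 2.00-fold lower. Aqp7, the channel through which adipocytes release glycerol, fell by 0.85 on the log2 scale. The largest difference belonged to Clec2g, a C-type lectin, at 7.83 ± 0.19 in control skin and 6.32 ± 0.29 on the arrays labelled Pparg null, or 2.83-fold (limma adjusted p = 0.00887).

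In all, 18 of 15174 tested genes passed a limma adjusted p of 0.05, 17 lower and 1 higher on the arrays labelled Pparg null. The secreted BMP regulators Chrdl1 and Bmper fell by 1.12 and 0.70 on the log2 scale. The protease inhibitor Serpina3n and the galectin-binding glycoprotein Lgals3bp fell by 1.01 and 0.74; Lgals3bp read 7.63 on labelled-null array 2 and 7.14 to 7.22 on the other arrays of that group. Trarg1, a regulator of the trafficking of the insulin-responsive glucose transporter, fell by 0.64, and the lactate receptor Hcar1 and the prostaglandin E2 receptor Ptger3 each fell by 0.63; Ptger3 read 6.43 on labelled-null array 1 and 6.64 to 6.66 on the others. Mgst1, a microsomal glutathione transferase, fell by 0.53. The remaining 4 genes that were lower, named after their values were seen to complete the count, were Btnl9 (-0.55), the acyl-CoA thioesterase Acot7 (-0.46), Hrct1 (-0.37) and Wfdc21 (-0.37). The gene that rose was Ms4a4d, a membrane protein of the Ms4a family, at 6.37 ± 0.06 in control skin and 6.84 ± 0.08 on the arrays labelled Pparg null (log2 values, SD, n = 4; limma adjusted p = 0.0194). Of the 18 genes, 12 differed by at least 1.5-fold and 5 by at least 2-fold, and all 12 of the former were lower.

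**Figure D1:**
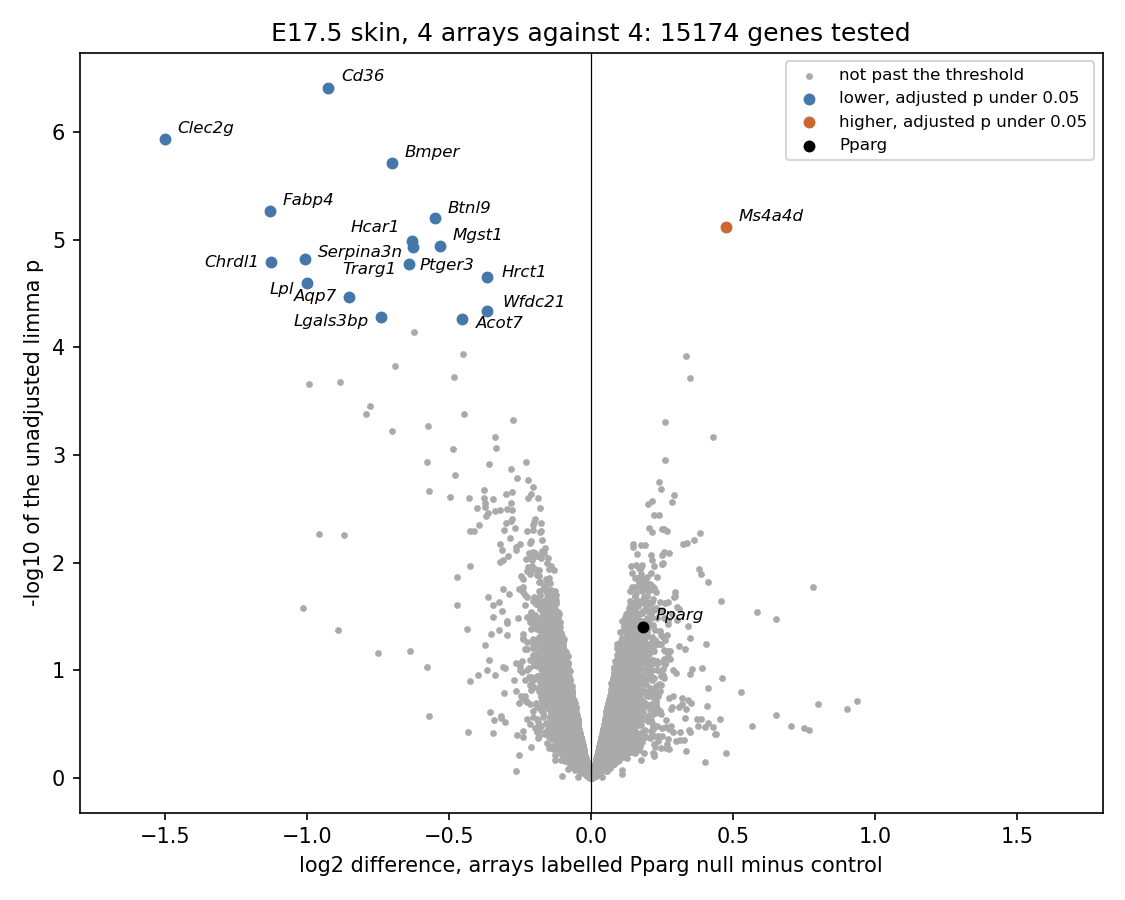
Each point is 1 of 15174 tested genes, with the log2 difference (arrays labelled Pparg null minus control, 4 arrays each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 17 genes past an adjusted p of 0.05 and lower lie to the left, from Clec2g at -1.50 to Wfdc21 at -0.37, Ms4a4d alone lies to the right at 0.47, and Pparg lies at 0.18.

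The number of genes past the threshold depended on single arrays. Without control array 2 or 3 it was 4, without control array 4 or labelled-null array 1 it was 5, and without labelled-null array 2 it was 3 and without labelled-null array 3 it was 9. Without control array 1 or labelled-null array 4 it was 15. Cd36 and Clec2g passed the threshold in all 8 fits with 1 array left out, and all 18 genes kept their direction in every alternative fit that tested them. Labelled-null array 4 stood apart on the first principal component of the tested genes outside the X and Y chromosomes (score of -21.7). Control array 1 came next at -8.62, then labelled-null array 2 at -3.12, and the rest ran from 4.44 to 9.02. Without control array 1 and labelled-null array 4 together, 14 genes passed, 11 of them among the 18. With the Xist value of each array as a covariate, 11 genes passed, and with every transcript cluster tested on its own, unnamed ones included, Cd36 alone passed.

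The white adipocyte list lay lower by limma's camera with a preset correlation (adjusted p = 1.69e-14), and missed the threshold with an estimated correlation (adjusted p = 0.0641). Of its 24 genes 19 were tested, 16 lay below control and 3 above, and the mean log2 difference was -0.36 (median -0.18). Of the 19, 4 passed over all genes, namely Cd36, Fabp4, Lpl and Aqp7, and 8 members passed adjusted over the list alone. Plin1, which coats the adipocyte lipid droplet, was at 7.10 ± 0.33 in control skin and 6.22 ± 0.18 on the arrays labelled Pparg null (log2 values, SD, n = 4), with a limma adjusted p of 0.128 over all genes and 0.0008 over the list alone. Cidea, another lipid droplet protein, lay 0.24 higher with an adjusted p of 0.582 over all genes and 0.00479 over the list alone. Adiponectin (Adipoq) lay under the brightness filter and was not tested; named after its values were seen, it read 5.40 ± 0.28 in control skin and 4.57 ± 0.23 on the arrays labelled Pparg null (log2 values, SD, n = 4). The mean of the list on each array also separated the groups, at 8.09 ± 0.10 against 7.73 ± 0.08 (SD, n = 4 each). The exact two-sided permutation p was 0.0286, the smallest possible, and 0.914 adjusted over the 48 lists. With that smallest p a single list could not pass after this adjustment, so the adjusted value decides nothing. Relative to all arrays the list mean was 0.04 on control array 1, 0.22 to 0.24 on the other control arrays and at most -0.06 on the arrays labelled Pparg null.

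**Figure D2:**
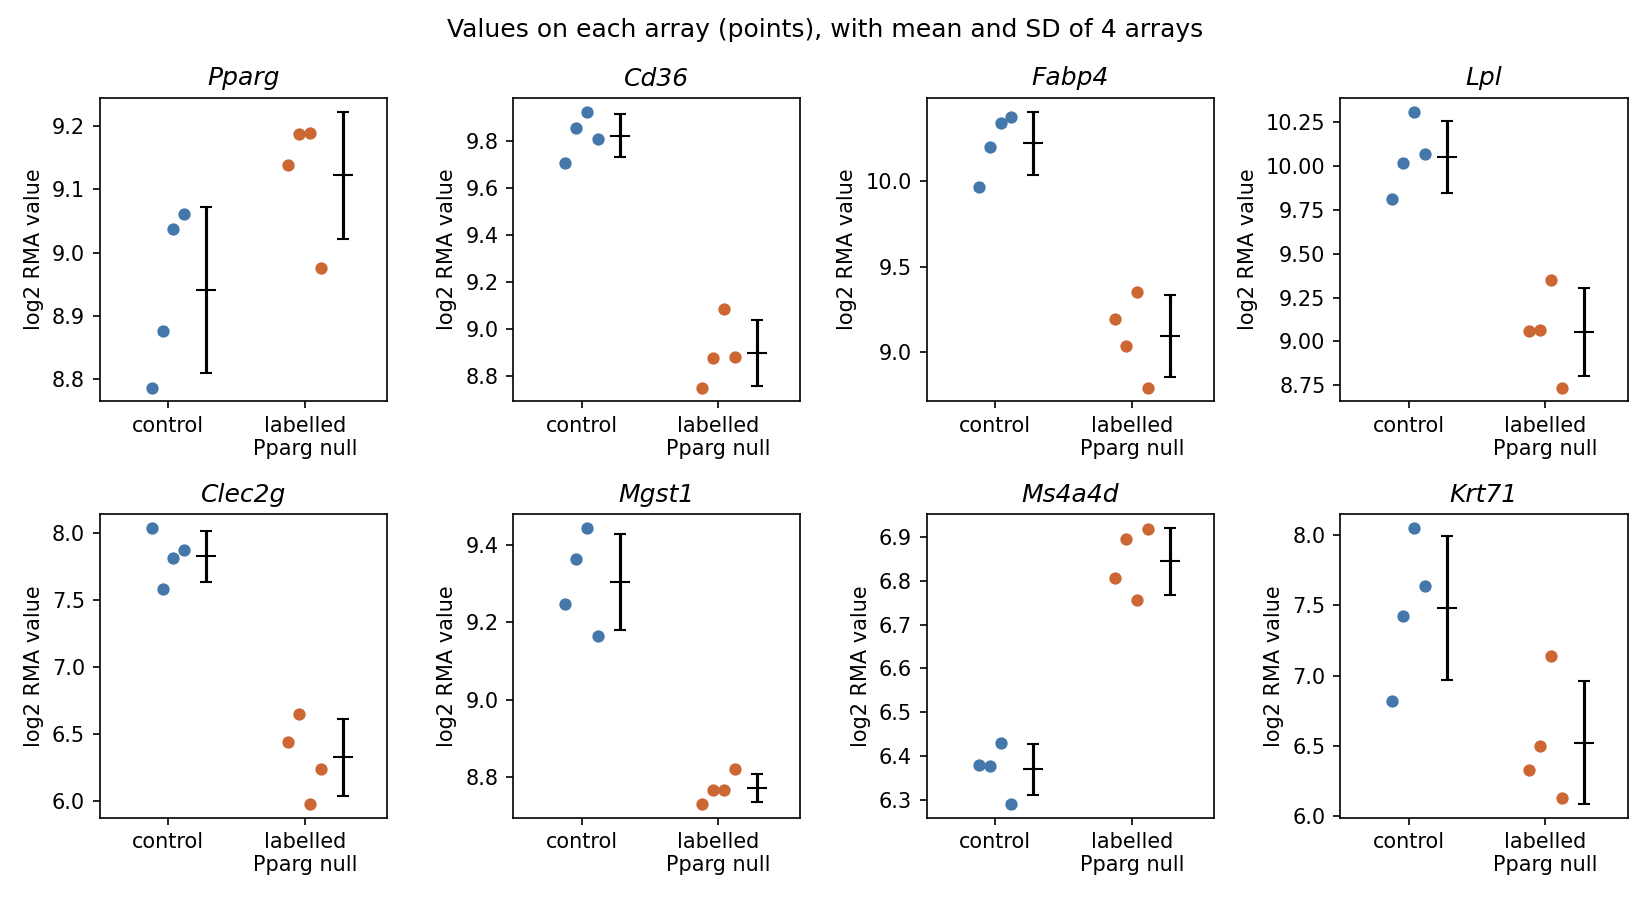
Log2 RMA values (vertical axes, scaled to each gene and not starting at 0) of 8 genes on the 4 control arrays and the 4 arrays labelled Pparg null, each point 1 array, with the mean and SD beside them. The groups are apart for Cd36, Fabp4, Lpl, Clec2g, Mgst1 and Ms4a4d, while Pparg and Krt71 overlap.

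Genes of the differentiating hair follicle lay lower on the arrays labelled Pparg null as a list, with no single member past the threshold. The list passed camera with the preset correlation (adjusted p = 0.000202) and not with an estimated correlation (adjusted p = 0.132). Of 26 tested genes of the hair shaft and inner root sheath, 22 lay below control, with a mean log2 difference of -0.19 and a median of -0.12. Krt71, a keratin of the inner root sheath, was at 7.48 ± 0.51 in control skin and 6.52 ± 0.44 on the arrays labelled Pparg null (log2 values, SD, n = 4; limma adjusted p = 0.821). The inner root sheath keratins Krt25 and Krt27 differed by -0.75 and -0.36, the hair keratin Krt31 by -0.23 and the hair keratin regulator Hoxc13 by -0.37, each with a limma adjusted p of 0.9995. On labelled-null array 4 Krt25 read 6.04, against 6.92 to 7.61 on the others of its group, and Hoxc13 read 6.12, against 6.65 to 6.96. Without 1 array Krt25 ranged from -1.03 to -0.44 and Hoxc13 from -0.49 to -0.21, both nearest 0 without labelled-null array 4. In limma 0 of the 26 members passed over all genes or over the list alone, and 3 had an unadjusted p under 0.05. The exact two-sided permutation p of its mean was 0.0571.

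Another 7 lists passed camera with the preset correlation, with small mean differences, and none of them passed with an estimated correlation. The lists of erythroid, cell cycle, interferon and glycolysis genes had an adjusted p of 0.893 with an estimated correlation, and those of the outer root sheath, cholesterol synthesis and dermal fibroblasts had 0.919, 0.938 and 0.967. With the preset correlation, lower on the arrays labelled Pparg null were cell cycle genes (22 of 23 tested members below control, mean -0.06; Ccna2 at -0.09 and Ccne2 at -0.14), interferon response genes (11 of 12 below, mean -0.13; Ifit3 at -0.32 and Oas2 at -0.16), dermal fibroblast and matrix genes (18 of 24 below, mean -0.06; Eln at -0.23 and Dpt at -0.09) and genes of the outer root sheath and bulge (12 of 14 below, mean -0.08; Krt79 at -0.37 and Lgr6 at -0.21). Higher with the preset correlation were erythroid genes (10 of 11 above, mean 0.17; Car1 at 0.26 and Car2 at 0.41), cholesterol synthesis genes (16 of 19 above, mean 0.09; Msmo1 at 0.27, Fdft1 at 0.26 and Sqle at 0.22) and genes of glycolysis and the hypoxia response (14 of 16 above, mean 0.07; Pdk1 at 0.17 and Ldha at 0.11). None of the members of these 7 lists passed limma over all genes, and the erythroid carbonic anhydrase Car1 alone passed adjusted over its list alone. Without 1 array the list means ranged from 0.10 to 0.23 (erythroid), 0.03 to 0.16 (cholesterol synthesis), 0.03 to 0.10 (glycolysis), -0.19 to -0.07 (interferon), -0.08 to -0.01 (dermal fibroblast), -0.10 to -0.04 (outer root sheath) and -0.08 to -0.05 (cell cycle). Among the members, Car2 ranged from 0.27 to 0.51, Sqle from 0.14 to 0.30, Pdk1 from 0.10 to 0.20, Ccne2 from -0.19 to -0.08, Oas2 from -0.23 to -0.10, Eln from -0.31 to -0.13, Krt79 from -0.49 to -0.16 and Lgr6 from -0.28 to -0.09. Single control arrays lay apart for Oas2 (6.95 on array 2 against 7.05 to 7.07), Dpt (11.85 on array 4 against 11.76 to 11.77) and Pdk1 (8.61 on array 4 against 8.90 to 8.91).

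Of the 48 lists, 9 passed camera with the preset correlation (6 lower, 3 higher) and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. By limma's fry, which asks whether a list's genes move one way on balance, the white adipocyte list alone passed (adjusted p = 0.0235). Other splits of the 8 arrays into 4 and 4 gave between 2 and 17 lists past the threshold with the preset correlation, and 19 of the 35 splits, the real one included, gave at least 9. The lists of the cell cycle, erythroid, hair shaft and white adipocyte genes passed in all 8 fits with 1 array left out. The other 5 did not pass without 1 of several arrays: cholesterol synthesis without labelled-null array 2 (adjusted p = 0.189), glycolysis without that array (0.276) or control array 4 (0.0934), interferon without labelled-null array 3 (0.0747) or 4 (0.0855), dermal fibroblast without control array 2 (0.0731), control array 4 (0.0934) or labelled-null array 4 (0.588), and outer root sheath without control array 3 (0.133), control array 4 (0.222) or labelled-null array 4 (0.472). With array weights the interferon (0.0578) and outer root sheath (0.242) lists did not pass, nor did the dermal fibroblast list without control array 1 and labelled-null array 4 together (0.131).

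**Figure D3:**
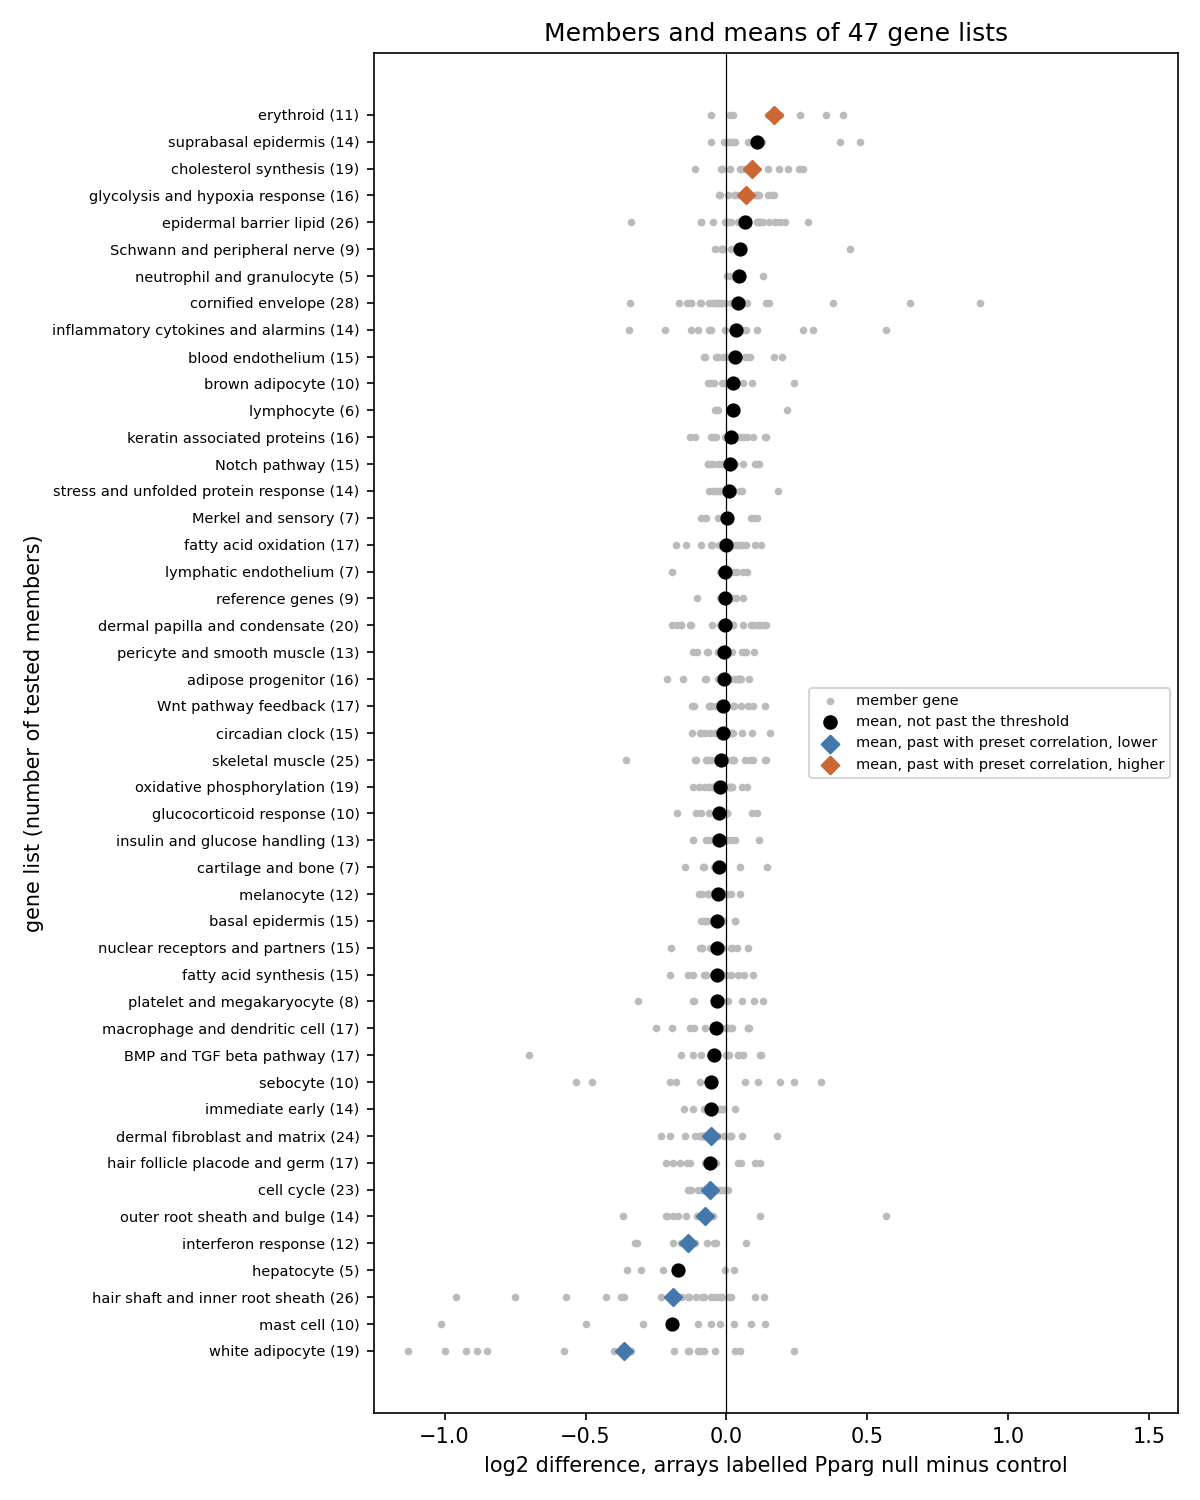
The log2 difference (arrays labelled Pparg null minus control) of each tested member (small points) and the mean of each gene list (large symbols), with the number of tested members in brackets and the sex-linked list left out. Diamonds mark the 9 lists past an adjusted p of 0.05 by camera with the preset correlation, from white adipocyte at -0.36 to erythroid at 0.17.

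Genes of the sebocyte list went both ways, and some of those above control, such as Fa2h, also stand in the epidermal barrier lipid list. Of 10 tested members of the sebocyte list, 5 lay below and 5 above control (mean -0.05, median -0.01; camera adjusted p = 0.191). Without 1 array the mean ranged from -0.12 to -0.01, and the list passed only without the filter on dim clusters (adjusted p = 0.0102). Mgst1 passed over all genes, and Mgst1, the melanocortin receptor Mc5r (-0.48), the lipid droplet protein Plin2 (-0.18) and Cidea (0.24) passed adjusted over the list alone. The stearoyl-CoA desaturase Scd1 differed by -0.20 (limma adjusted p = 0.9995), with -0.30 to -0.11 when 1 array was left out. By fry in either direction, the sebocyte list passed (adjusted p = 3.73e-06), as did the white adipocyte list (0.000489) and the BMP and TGF beta list (0.00288), in which Bmper was the one member past the threshold. The mean of the BMP and TGF beta list was -0.04, its median 0.01 and its camera direction lower (adjusted p = 0.638), with means of -0.06 to -0.02 when 1 array was left out.

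Mast cell genes missed the threshold as a list (mean -0.19, median -0.08, 7 of 10 below control, camera adjusted p = 0.0655). It passed in 4 of 8 fits with 1 array left out, where the adjusted p ran from 0.00598 to 0.474, and had an adjusted p of 0.893 with an estimated correlation. The mast cell protease Mcpt4 was at 10.42 ± 0.16 in control skin and 9.92 ± 0.25 on the arrays labelled Pparg null (log2 values, SD, n = 4; limma adjusted p = 0.643), and passed adjusted over the list alone. The mast cell tryptase Tpsab1 differed by -1.01 with an SD of 0.97 among the control arrays (limma adjusted p = 0.9995), and passed only without control array 2, where it read 6.13 against 7.74 to 8.40 on the other control arrays (adjusted p = 0.0242).

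Sex-linked transcripts were balanced between the groups. Xist, which is expressed from the inactive X chromosome of females, read 12.24 and 12.27 on control arrays 1 and 4 and 12.17 and 12.10 on labelled-null arrays 3 and 4, against 4.86 to 5.39 on the other 4 arrays. The Y-linked Eif2s3y read 9.37 to 9.68 on those other arrays and 3.48 to 4.25 on the Xist-high ones, and Kdm5d and Uty followed it. Each group thus held 2 arrays with high Xist and 2 with high Y-linked transcripts.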

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

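In groups of 4 arrays, 7 of 214 groups of values had 1 array far from the rest of its group, where chance gives about 11, or 1 in 20. These values are given without explanation. The gap between the far array and its nearest neighbour is stated as a share of the group's whole range.

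Among genes past the threshold, Lgals3bp read 7.63 on labelled-null array 2 and 7.14 to 7.22 on the others (gap 0.831), and Ptger3 read 6.43 on labelled-null array 1 and 6.64 to 6.66 on the others (gap 0.921); both far values still lay below all control values. Among other named genes, the antiviral gene Oas2 read 6.95 on control array 2 against 7.05 to 7.07 (gap 0.883), the matrix gene Dpt read 11.85 on control array 4 against 11.76 to 11.77 (gap 0.862), and Pdk1, a kinase that restrains pyruvate oxidation, read 8.61 on control array 4 against 8.90 to 8.91 (gap 0.953). The hair germ signal Shh read 7.84 on labelled-null array 4 against 8.12 to 8.18 (gap 0.834).

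The mean of the white adipocyte list, relative to its mean over all 8 arrays, was 0.04 on control array 1 and 0.22 to 0.24 on the other control arrays (gap 0.902). The labelled-null array nearest to it, array 3, was at -0.06. Without control array 1, Plin1 passed the limma threshold (adjusted p = 0.0426, with 0.0267 to 0.479 over its alternatives), and the count of genes past the threshold was 15.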

How the results depend on the processing

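All 18 genes past the threshold kept their direction in all 337 values under other settings (1 value per gene and setting that tested it), and 205 of these stayed past it. The count of 18 stayed between 12 and 21 under other filters, scalings, priors, array weights, clusters averaged per gene, a 1.5-fold minimum, the suprabasal covariate, or without control array 1 and labelled-null array 4. It was 3 at an adjusted p of 0.01 (Cd36, Clec2g and Bmper), 1 with every transcript cluster tested on its own and 11 with Xist as a covariate; both covariates and the fit without these 2 arrays were chosen after seeing the data. Leaving out 1 array gave 3 to 15 genes and 7 to 13 lists; fits with fewer arrays have less power. The replicate numbers did not pair the arrays: same-numbered arrays deviated from their group means with r = -0.31, 0.20, 0.05 and -0.03 across all tested genes, where no array correlated best with its own number (without X and Y genes r was -0.22, 0.022, 0.20 and -0.15, and control array 3 did), and the replicate block left 1 gene (Cd36) and 10 lists. Of 48 lists, 9 passed in the main test, 0 with an estimated correlation and 1 by fry. The estimate allows for members that vary together, but this alone does not account for every lost call. For the hair shaft and inner root sheath list the estimate was 0.015, near the preset 0.01. Its unadjusted camera p was still 8.4e-06 with the preset and 0.0055 with the estimated correlation. Pparg lay 0.13 to 0.23 higher on the arrays labelled Pparg null under all settings and never passed. The 39 lists not past the threshold stayed so in 637 of 663 values under other settings. The epidermal barrier lipid list ranged from -0.0709 to 0.158 without 1 array, passed lower without labelled-null array 4 and passed higher without labelled-null array 1 or 3, and the skeletal muscle list ranged from -0.121 to 0.0496, passed lower without labelled-null array 3 and passed higher without labelled-null array 4; the cause was not tested. Genes under the 30th percentile of their array, such as Adipoq, are near the background of these arrays, where log2 differences are compressed. Among tested genes named here, Car1 lay there on the control arrays, Hcar1 on labelled-null arrays 1, 2 and 3, and Krt31 on labelled-null arrays 1 and 4.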

Other observations

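The lists of nuclear receptors, fatty acid synthesis, fatty acid oxidation, adipose progenitors and brown adipocytes did not pass camera. Nr1h3, the oxysterol receptor LXR alpha, differed by -0.20 (limma adjusted p = 0.9975) and stood in the nuclear receptor list (mean -0.03, 11 of 15 members below control, camera adjusted p = 0.194). Srebf1 and Fasn, the regulator and the main enzyme of fatty acid synthesis, differed by -0.14 and -0.08, each with a limma adjusted p of 0.9995 (list mean -0.03, camera adjusted p = 0.218). The fatty acid oxidation list had a mean of -0.0001, a median of 0.02 and a camera direction of higher (adjusted p = 0.9895). Markers of adipose progenitors went both ways, with a mean of -0.01, a median of 0.02 and a camera direction of lower (adjusted p = 0.948), and Zfp423 and Gdf10 differed by -0.15 and -0.21 (limma adjusted p = 0.9995). The brown adipocyte list had a mean of 0.02 (camera adjusted p = 0.641), and Cidea was its one member past the threshold adjusted over the list alone. Without 1 array these list means ranged from -0.05 to -0.02 (nuclear receptors and fatty acid synthesis), -0.02 to 0.03 (fatty acid oxidation), -0.02 to -0.002 (adipose progenitors) and -0.01 to 0.05 (brown adipocytes), none past the threshold, and Fasn ranged from -0.11 to -0.05.

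Epidermal differentiation varied more between arrays than between groups. The mean of the suprabasal epidermis list, relative to all arrays, was 0.64 on labelled-null array 4, -0.45 on control array 2 and -0.38 on labelled-null array 1, and the groups differed by 0.11 (exact two-sided permutation p = 0.771; camera adjusted p = 0.218). Without 1 array that difference ran from -0.09 (without labelled-null array 4) to 0.25 (without labelled-null array 1, the one such fit past the threshold, adjusted p = 0.00754), and it was also below 0 without control array 2 (-0.02). Krtdap, a marker of suprabasal keratinocytes, read 11.77 ± 0.15 in control skin and 11.89 ± 0.14 on the arrays labelled Pparg null (log2 values, SD, n = 4), and their difference ran from 0.05 to 0.17 without 1 array. The hair placode and germ list had a mean of -0.06 (camera adjusted p = 0.184), with Shh at -0.16 and Foxi3 at -0.13. Without 1 array the list mean ran from -0.09 to -0.01, Shh from -0.24 to -0.09 and Foxi3 from -0.18 to -0.06; the list passed without control array 1 (adjusted p = 0.0286) or labelled-null array 2 (0.0222). In the dermal papilla list, with a mean of -0.01, a median of 0.02 and a camera direction of higher (adjusted p = 0.948), Rspo3 differed by 0.13 and Fgf10 by -0.16, and the list mean ran from -0.04 to 0.05 without 1 array. The chemokine Ccl7 differed by -0.35 (limma adjusted p = 0.643).

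For the patterns weighed next, the tests of tissue depth, of exchanged arrays and groups, of single probes and of splits for the hair list were chosen after the results were seen; the suprabasal covariate was added once the patterns were known, with its prediction written ahead of its fit.

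The fall of 17 genes on the arrays labelled Pparg null was weighed against chance and against the state of the samples. Of the 35 splits of the 8 arrays, 1, the real one, gave as many as 18 genes; the highest of the others gave 4, namely Xist, Eif2s3y, Kdm5d and Uty in the split by high and low Xist, which argues against chance for the count, 1 of 35 being the smallest share that these arrays can give. With the suprabasal list mean as a covariate the median log2 difference of the 17 genes was -0.69, against -0.70 without it. That list mean hardly differed between the groups, at 10.49 ± 0.27 in control skin and 10.6 ± 0.43 on the arrays labelled Pparg null (SD, n = 4; exact two-sided permutation p = 0.771). The covariate could therefore move the median little, and this fit cannot decide on epidermal maturity. For the white adipocyte list, less deep tissue in the dissection would lower the skeletal muscle list, from the layer under the fat, at least as much. The difference of muscle minus adipocyte means was 0.345 higher on the arrays labelled Pparg null (exact two-sided permutation p = 0.0286, the smallest possible). Nearly all of it was the adipocyte difference, as the muscle mean itself was -0.02 apart with opposite camera direction (adjusted p = 0.948). The muscle mean varied between arrays (SD 0.10 in control skin and 0.23 on the arrays labelled Pparg null), and its difference ran from -0.12 to 0.05 without 1 array. Muscle thus did not fall with the adipocyte list, but whether less of the fat layer was taken cannot be decided from it. The genotype, fewer adipocytes and less transcript per adipocyte are among the causes that stay open as untested. Each value averages over the tissues of full-thickness skin, so the cell type behind these falls was not tested either.

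The Pparg cluster reading 0.183 higher on the arrays labelled Pparg null raises the question of labels. Exchange of single arrays would place arrays inside the other group's range of the white adipocyte list, and 0 of 8 lay there. The mean of that list was already known to separate the groups, so this and the comparison for whole groups below rest on the same observation. Probes outside the deleted part may keep their signal in a deleted gene; this cannot be told apart from an intact gene, because the cluster is summarized over probes and the deleted part is not given in the sources used here. An exchange of whole groups would place the white adipocyte list, whose genes PPARgamma is known to drive, higher on the arrays labelled Pparg null, and its mean was -0.365 apart (exact two-sided permutation p = 0.0286, the smallest possible), which argues against it as far as that knowledge holds in this skin.

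With the suprabasal list mean as a covariate the mean log2 difference of the hair shaft and inner root sheath list was -0.176, against -0.189 without it. The list stayed past the threshold by camera with the preset correlation (adjusted p = 4.16e-05). Because the covariate hardly differed between the groups, it could change this difference little, and the fit cannot decide on epidermal maturity. Without the covariate the call of the hair shaft and inner root sheath list was lost with an estimated correlation (adjusted p = 0.132) and by fry (0.264), with 7.68e-08 to 0.264 over all its alternatives. The difference in its mean was as large in 2 of the 35 splits, the real one included, with 0.23 the largest of the others in size, so chance cannot be excluded. The same holds for the number of lists: 19 of the 35 splits gave at least the 9 of the real split, with 17 the highest of the others. A difference in hair follicle stage between the embryos may also move this list and was not tested.

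At an unadjusted p under 0.05 limma gave 548 genes for the real split (319 lower), where 759 are expected by chance, and 202 to 2453 for the 34 other splits. Groups without overlap were seen in 372 genes, where chance gives 434.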
